A study of Homo sapiens with 8 samples.

How the data were processed

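Gene expression was measured on Affymetrix human arrays with 3′ probe sets in 8 samples of 2 human cell lines, Caco-2 and HUG1N. Each line had 2 control arrays and 2 arrays of cells given a short hairpin RNA (shRNA) against GATA6. Per the labels' protocols, infected cells were selected with puromycin, total RNA was extracted with Trizol, and biotin-labelled RNA was made with a 3′ in vitro transcription kit. The labels do not say what the control cells received, how long selection lasted, or whether the arrays of a group came from separate cultures. The p-values given here therefore measure only the spread between these arrays, which may be technical.

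The deposited values are log2 expression values, 1 per probe set and array, made by the authors with GCRMA per the submitters' processing notes. GCRMA corrects background by probe base content, equalises the arrays' distributions and summarises the probes of a probe set. Its version and settings are not given in the sources used here. All 8 columns shared a lowest value of 2.08, at which 28.7 to 29.9% of the probe sets of an array lay, and their medians ran from 4.73 to 4.98. The columns were therefore treated as normalized together, and levels in the 2 lines were compared. No further scaling was applied in the tests reported as main results. The floor means that a fold change against a gene near 2.08 has no fixed size. Where no array of a group exceeded log2 4, the change is given as a bound, the mean of the brighter group against 4. Such a bound, written as at least, makes no allowance for the spread between the arrays of the brighter group. The number of arrays limits the precision of every value.

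Probe sets were named through the platform's annotation table. Of 22277 probe sets, 19070 had 1 gene symbol, 1043 had several and 2164 had none here. For 19058 of those with 1 symbol the Entrez identifier matched a table of GRCh38.p14 genes, which was used for current symbols only. No genome was used here, so no positions are given. The brightest probe set over all 8 arrays stood for each of 11963 genes. A gene was tested if its log2 value was over 4 in at least 2 arrays, which kept 7696 genes and left out 4267. Probe sets with several symbols or none entered no gene-level test.

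Tests were run with limma 3.58.1 in R 4.3.3 (lmFit on the means of the 4 groups, then eBayes), with Benjamini-Hochberg adjustment over the 7696 genes of each comparison. Genes with an adjusted p under 0.05 are called. All 8 arrays shared 1 estimate of the spread per gene, with 4 residual degrees of freedom and a prior of 2.17 degrees of freedom at a standard deviation of 0.0989. Arrays of a group at the floor hardly vary, which lowers this estimate. For genes at the floor in some groups, SE and p can therefore be too small for the other groups. The comparisons were shRNA against control in each line, the difference between these effects, and HUG1N control against Caco-2 control. Overlap of calls between lines was tested with Fisher's exact test, one-sided, per direction.

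The groups, tests, alternatives, rule for named genes and 26 gene lists were fixed before the data were examined. The lists hold 786 genes, of which 526 were tested, and cover gut, gastric and liver-type lineages, signalling and stress responses, cell cycle, metabolism, markers of other cell types and housekeeping controls. The 24 lists with at least 5 tested genes were tested with limma's camera, a two-sided test against the other genes with a preset correlation of 0.01 between genes, adjusted over the 48 tests of both lines. Named genes were GATA6, the 12 largest called rises and falls per line, the 8 genes called the same way in both lines with the largest smaller change, and the 8 largest called differences between lines. For the controls the rule took the 6 largest differences each way, and for each list and line up to 4 members with the smallest p. Of 114 pairs of such a gene and a comparison with several probe sets, 3 had a probe set that moved the other way at an unadjusted p under 0.05, those of CFLAR, ELF3 and GSTA1 in HUG1N.

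The fit was tested on simulated data drawn from each line's control means and each gene's spread, over 7696 genes, with changes put into genes over log2 6. In simulated Caco-2 comparisons it called 43.3% of genes changed by 0.5 log2 units, 89.6% of those changed by 1 and 93.9% of those changed by 2. The shares for HUG1N were 49.3, 85.1 and 97.0%. False calls made up 6.79% and 6.67% of the calls. In each simulated comparison only 67, 67 and 66 genes were changed by 0.5, 1 and 2 log2 units. The real comparisons called 2982 genes in Caco-2 and 3746 in HUG1N. The adjustment is less strict where many genes change, so these shares may not carry over to the real tests. Alternatives covered the filter, further normalization, the variance model, each line alone, the choice of probe set, a floor at log2 4, a 2-fold minimum, the replicate number as a block, leaving out each array, and for lists an estimated correlation or limma's fry.

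RNA quality was read from the control probe sets on the arrays: the 3′ minus 5′ value of ACTB and GAPDH, the poly-A spikes, and the hybridisation controls added to each labelled sample.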

Results

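The series compared 2 human cancer cell lines with and without an shRNA against GATA6, a zinc-finger transcription factor of gut endoderm, within a study of its oncogenic role in the stomach. Caco-2 is a colorectal adenocarcinoma line that acquires enterocyte features in culture. HUG1N, also called HuG-1 in the labels, is a gastric cancer line. There were 4 groups of 2 arrays each, and 7696 genes were tested. Arrays of a group correlated at r of 0.995 to 0.997 across genes. An shRNA array and a control array of the same line correlated at 0.962 to 0.966, and arrays of different lines at 0.697 to 0.745.

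GATA6 itself fell by a small amount in Caco-2. Its log2 value was 12.54 ± 0.13 (SD, n = 2) in control and 12.12 ± 0.15 (SD, n = 2) in shRNA cells. The change was -0.42 (SE 0.10, limma adjusted p = 0.0224), which left 74.9% of the control level (95% interval 62.9 to 89.2%). In HUG1N the values were 12.50 ± 0.06 and 12.24 ± 0.03 (SD, n = 2 each). That change of -0.25 (SE 0.10) did not pass the adjusted test (limma adjusted p = 0.0879), and the shRNA cells held 83.9% of the control level (95% interval 70.5 to 99.9%). Both shRNA arrays lay below both control arrays in each line. The difference between the lines' effects was 0.16 (SE 0.15, limma adjusted p = 0.396). GATA6 had 1 probe set, and its place on the transcript is not known here. The Caco-2 call was lost without control replicate 1 (-0.32, adjusted p = 0.112), without shRNA replicate 2 (-0.31, adjusted p = 0.0949), with no filter (adjusted p = 0.0562) and with the line fitted alone (adjusted p = 0.0724), within a range of 0.00422 to 0.112 over 18 alternatives.

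**Figure D1:**
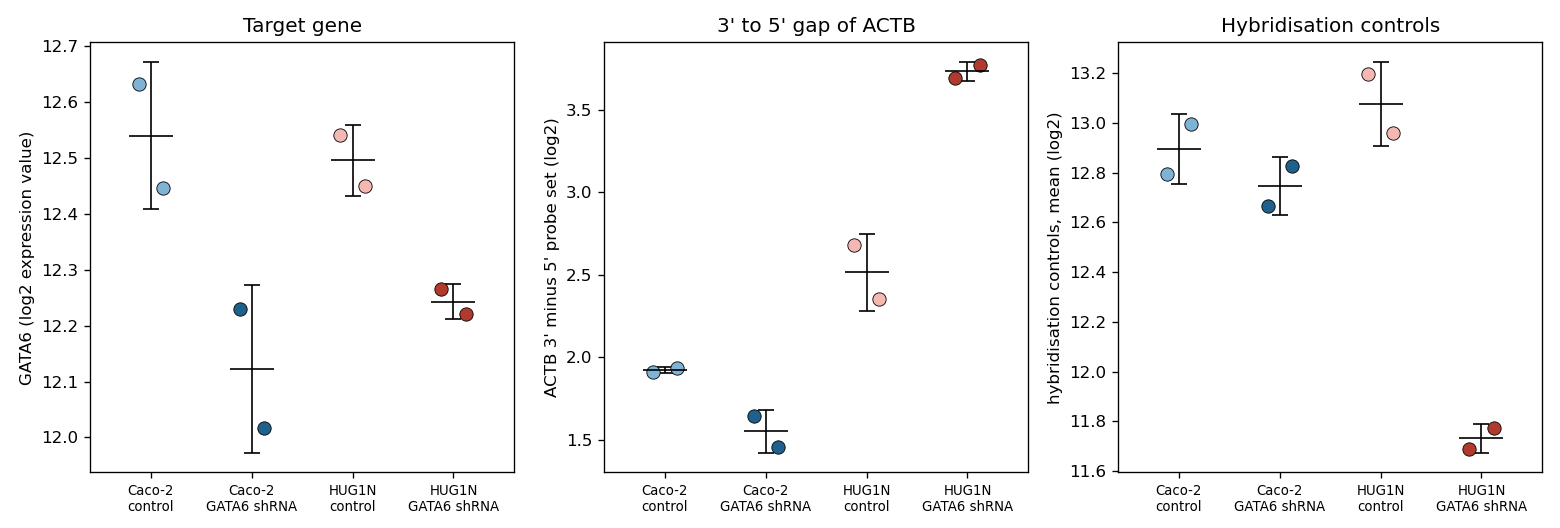
Log2 values per array (points) with the mean and SD of each group of 2 arrays (bars) for GATA6, for the 3′ minus 5′ gap of ACTB and for the mean of the hybridisation controls; the axes do not start at 0. GATA6 was 12.12 in Caco-2 shRNA and 12.24 in HUG1N shRNA cells, and the ACTB gap was 3.73 in HUG1N shRNA cells against 2.51 in their controls.

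In Caco-2, the largest rises with the shRNA were of genes that the control arrays barely registered, and the largest falls included LGR5 and enzymes of steroid metabolism. SCEL, a protein of cornified squamous cells, rose from 3.49 to 10.95 on the log2 scale, at least 124-fold, and VGLL1, a cofactor of TEAD transcription factors, rose from 2.67 to 10.64, at least 99.6-fold. LGR5, the R-spondin receptor of intestinal stem cells, fell from 9.03 to 3.47, at least 32.8-fold. SULT2A1, a hydroxysteroid sulfotransferase, changed by -6.06 (SE 0.44, adjusted p = 2.03e-04), and HSD3B1, a steroid dehydrogenase, by -5.78 (SE 0.42, adjusted p = 2.16e-04). SULT2A1 and HSD3B1 were over log2 4 in 1 of the 2 shRNA arrays. The SD of HSD3B1 was 0.24 in Caco-2 control and 1.01 in Caco-2 shRNA arrays, but 0 in both HUG1N groups, near the floor. Its SE pools the 4 groups and so understates the spread in Caco-2.

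The other leading rises in Caco-2 included the placental alkaline phosphatase ALPP (at least 28.3-fold), the potassium channel KCNJ16 (at least 46.1-fold) and the retinoid-responsive phospholipase PLAAT4 (at least 35.0-fold). The placental galectin LGALS14 rose at least 17.5-fold, the proton pump subunit ATP6V1B1 at least 16.8-fold and the methyltransferase NNMT at least 39.5-fold. The platelet chemokine PPBP rose at least 15.3-fold, the sialic acid-binding lectin SIGLEC6 at least 17.7-fold and the interferon-induced IFIT1 at least 24.8-fold. ANXA1, a phospholipid-binding annexin, changed by 5.99 (SE 0.41, adjusted p = 1.70e-04) from a control mean of 3.74, with 1 of the 2 control arrays over log2 4. The probe sets of ALPP and SIGLEC6 can pick up near-identical relatives, so those values are uncertain as to the gene.

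The other leading falls in Caco-2 included ADAM23 (at least 13.7-fold) and BTNL8, a butyrophilin-like protein of gut epithelium (at least 32.3-fold). The endosomal trafficking gene VPS35L fell at least 16.3-fold, the plasma protein gene ITIH2 at least 19.3-fold, ADAM22 at least 5.24-fold and DZANK1 at least 5.59-fold. The receptor gene ROR1 fell at least 5.53-fold. Limma put the phospholipid flippase gene ATP10D at -4.37 (SE 0.53, adjusted p = 0.00152) and TFF2, a trefoil peptide of gastric mucus, at -4.22 (SE 0.20, adjusted p = 3.77e-05).

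Lipid-handling and plasma protein genes fell as lists in Caco-2, in arrays whose ACTB gap was 1.55 against 1.92 in control. Of 16 tested genes for apolipoproteins and lipid absorption, 12 fell and 0 rose, and the counts adjusted over the list alone were equal (camera adjusted p = 1.77e-04; adjusted p = 0.322 with an estimated correlation). APOA1 changed by -1.62 (SE 0.06), APOH by -2.34 (SE 0.16) and the triglyceride synthesis enzyme DGAT1 by -1.31 (SE 0.07). Of 21 liver-type plasma protein genes, 13 fell and 4 rose, or 14 and 4 adjusted over the list alone (camera adjusted p = 0.00236; adjusted p = 0.322 with an estimated correlation). Haptoglobin (HP) changed by -3.78 (SE 0.06) and albumin (ALB) by -2.94 (SE 0.07), while complement C5 rose at least 9.92-fold.

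Cell cycle genes also fell in Caco-2, in the same arrays with the ACTB gap of 1.55 against 1.92. In the list for DNA replication and G1/S, 21 of 39 fell and 2 rose, or 25 and 2 adjusted over the list alone (camera adjusted p = 2.32e-04; adjusted p = 0.400 with an estimated correlation). The helicase subunits MCM6 and MCM2 changed by -0.85 (SE 0.09) and -0.64 (SE 0.10), and GINS4 by -1.15 (SE 0.18). In the list for mitosis and G2/M, 13 of 40 fell and 0 rose, with equal counts adjusted over the list alone (camera adjusted p = 2.32e-04; adjusted p = 0.400 with an estimated correlation). The separase gene ESPL1 changed by -1.08 (SE 0.10) and the kinesin gene CENPE by -0.64 (SE 0.10).

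Epithelial and signalling lists rose in Caco-2, again with the ACTB gap of 1.55 against 1.92. Of 27 genes for epithelial junctions and keratins, 15 rose and 2 fell, or 16 and 2 adjusted over the list alone (camera adjusted p = 5.01e-04; adjusted p = 0.322 with an estimated correlation). KRT19 changed by 1.56 (SE 0.09), KRT8 by 1.58 (SE 0.12), KRT18 by 1.20 (SE 0.08) and the tight junction gene CLDN4 by 1.49 (SE 0.11). Of 27 immediate early and MAPK feedback genes, 14 rose and 1 fell, or 15 and 1 adjusted over the list alone (camera adjusted p = 0.00179; adjusted p = 0.322 with an estimated correlation). The phosphatase genes DUSP5 and DUSP1 changed by 2.89 (SE 0.07) and 1.21 (SE 0.07), and SPRY1, an inhibitor of receptor tyrosine kinase signalling, by 1.61 (SE 0.09).

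The remaining lists were not called in Caco-2, although many of their members were. Of 20 BMP and TGF-beta targets, 10 rose and 2 fell (adjusted p = 0.0665), with BAMBI at 3.51 (SE 0.12) and ID1 at 2.40 (SE 0.11). Of 22 mesenchymal and matrix genes, 10 rose and 3 fell (adjusted p = 0.0665), with CCN1 at 2.63 (SE 0.15). Of 34 interferon response genes, 13 rose and 3 fell (adjusted p = 0.103), with ISG15 at 1.89 (SE 0.14) and HERC5 at 2.38 (SE 0.18), and 8 of the 34 had no Caco-2 array over log2 4. Of 8 goblet and enteroendocrine genes, 5 fell and 1 rose (adjusted p = 0.0665), with TFF3 at -1.47 (SE 0.08). Of 15 Wnt targets and stem cell genes, 5 fell and 2 rose (adjusted p = 0.267), with CD44 at -1.12 (SE 0.09). Of 20 enterocyte genes, 4 rose and 7 fell (adjusted p = 0.986), with CEACAM6 at 4.06 (SE 0.06) and carbonic anhydrase CA2 at -2.26 (SE 0.16). Of 12 gastric genes, 2 rose and 3 fell (adjusted p = 0.557), with TFF1 at -3.20 (SE 0.11), and 6 of the 12 had no Caco-2 array over log2 4. For these 7 lists the counts adjusted over the list alone were equal.

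Of 16 gut endoderm transcription factors, 2 rose and 8 fell, or 3 and 8 adjusted over the list alone (adjusted p = 0.150), with SOX9 at -1.12 (SE 0.15) and ELF3 at 1.40 (SE 0.10). Of 29 unfolded protein response genes, 11 rose and 6 fell, or 12 and 6 adjusted over the list alone (adjusted p = 0.178). Of 31 glycolysis and hypoxia genes, 6 rose and 4 fell, or 5 and 4 adjusted over the list alone (adjusted p = 0.557), with the hexokinase gene HK1 at 4.22 (SE 0.12). Of 26 xenobiotic and steroid metabolism genes, 6 rose and 10 fell, or 6 and 11 adjusted over the list alone (adjusted p = 0.192), with CYP1B1 at 3.83 (SE 0.19; 1 of the 2 control arrays over log2 4) and GSTA1 at -2.74 (SE 0.10). Counts were equal adjusted over the list alone for the other lists. Of 18 p53 targets 4 rose and 2 fell (adjusted p = 0.463), and of 21 apoptosis regulators 4 rose and 2 fell (adjusted p = 0.865). Of 22 NF-kB and cytokine genes 4 rose and 6 fell (adjusted p = 0.915), with the prostaglandin synthase PTGS2 at 3.04 (SE 0.07) and the chemokine CXCL8 at least 11.9-fold lower, and 6 of the 22 had no Caco-2 array over log2 4. Of 23 cholesterol synthesis genes 3 rose and 5 fell (adjusted p = 0.915), and of 6 metallothioneins 2 rose and 0 fell (adjusted p = 0.135). Of 34 ribosomal protein genes 0 were called by limma (list adjusted p = 0.446), and of 12 housekeeping genes 1 rose and 2 fell (adjusted p = 0.986). Median and mean had opposite signs for the enterocyte, gastric, NF-kB and cholesterol lists, and the housekeeping test pointed up while its median and mean were -0.01 and -0.02.

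Over all genes, limma called 2982 in Caco-2, 1504 higher and 1478 lower with the shRNA, of which 742 changed at least 2-fold. The ACTB gap was 1.92 ± 0.02 in control and 1.55 ± 0.13 in shRNA arrays (SD, n = 2 each), that of GAPDH 0.16 ± 0.01 and 0.07 ± 0.02, and the hybridisation controls 12.90 ± 0.14 and 12.75 ± 0.12. Of 14 fibroblast markers with a probe set 3 exceeded log2 4 in a group, and of 15 immune markers 2 did. Lumican (LUM), a fibroblast marker, rose at least 11.6-fold in Caco-2 shRNA cells to 7.53. The number of called genes was 1985 without control replicate 1 and 1895 without control replicate 2.

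In HUG1N, the largest falls with the shRNA included the interleukin-1 genes, and the largest rises were mostly of genes that the control arrays barely registered. IL1B and IL1A, the interleukin-1 cytokines, fell at least 37.0-fold and at least 25.7-fold, from 9.21 and 8.68 on the log2 scale to 2.17 and 3.31. CLIC5, an intracellular chloride channel protein of microvilli, rose from 2.62 to 9.14, at least 35.4-fold. MMP1, the interstitial collagenase, changed by -4.12 (SE 0.20, adjusted p = 6.58e-05) and KRT20, a keratin of intestinal epithelium, by 4.23 (SE 0.41, adjusted p = 5.41e-04), with KRT20 over log2 4 in 1 of the 2 control arrays. The shRNA arrays of this line also differed in RNA quality measures. The ACTB gap was 2.51 ± 0.23 in control and 3.73 ± 0.06 in shRNA arrays, and that of GAPDH 0.41 ± 0.04 and 0.63 ± 0.06. The hybridisation controls were 13.08 ± 0.17 and 11.73 ± 0.06 (SD, n = 2 each).

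Other leading rises in HUG1N were the antiviral gene RSAD2 (at least 20.2-fold), coagulation factor F5 (at least 18.6-fold), the axonemal gene DRC9 (at least 12.4-fold) and the transporter genes SLC6A14 (at least 9.28-fold) and SLCO2B1 (at least 16.5-fold). DNAI7, which belongs to dynein arms of motile cilia, changed by 4.33 (SE 0.19, adjusted p = 5.33e-05). EFHC2 rose at least 8.68-fold and CFAP44 at least 3.84-fold. The acid phosphatase gene ACP3 changed by 4.52 (SE 0.32, adjusted p = 2.04e-04) and KANSL1L by 4.33 (SE 0.59, adjusted p = 0.00178). Both were over log2 4 in 1 of the 2 control arrays.

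Other leading falls in HUG1N included the GTPase gene RAC2 (at least 8.64-fold), the lymphocyte kinase gene LCK (at least 9.07-fold) and the cytokine subunit gene IL23A (at least 6.69-fold). BCL2L14 fell at least 18.0-fold, PLCB4 at least 4.92-fold and the interferon-induced IFI27 at least 7.95-fold. GREB1L changed by -3.85 (SE 0.15, adjusted p = 4.54e-05) and the secreted ribonuclease gene RNASE1 by -3.79 (SE 0.42, adjusted p = 8.37e-04). The pseudogene POU5F1P3 fell at least 6.03-fold, a value its near-identical relatives may share.

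Glycolysis and metallothionein genes fell as lists in HUG1N, in arrays whose ACTB gap was 3.73 against 2.51. Of 31 glycolysis and hypoxia genes, 21 fell and 0 rose, with equal counts adjusted over the list alone (camera adjusted p = 3.76e-05; adjusted p = 0.400 with an estimated correlation). The kinase PDK1 changed by -2.05 (SE 0.10), enolase ENO2 by -2.89 (SE 0.21), GPI by -1.03 (SE 0.09) and PFKP by -0.91 (SE 0.08). All 6 metallothioneins tested fell, also adjusted over the list alone (camera adjusted p = 0.00472; adjusted p = 0.322 with an estimated correlation). MT1G changed by -2.51 (SE 0.20), MT1X by -1.99 (SE 0.24) and MT2A by -1.91 (SE 0.21). These genes are near-identical, so the values may be shared among them.

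Mitotic, inflammatory and ribosomal lists fell in the same HUG1N arrays, with the same ACTB gap. In the list for mitosis and G2/M, 18 of 40 fell and 3 rose, with equal counts adjusted over the list alone (camera adjusted p = 0.0106; adjusted p = 0.493 with an estimated correlation). The kinase AURKB changed by -1.48 (SE 0.10), BUB1B by -0.99 (SE 0.07) and TACC3 by -0.90 (SE 0.08). Of 22 NF-kB and inflammatory cytokine genes, 11 fell and 4 rose, or 11 and 5 adjusted over the list alone (camera adjusted p = 0.0335; adjusted p = 0.322 with an estimated correlation). IL32 changed by -2.64 (SE 0.17) and the NF-kB inhibitor TNFAIP3 by -1.32 (SE 0.07). Of 34 ribosomal protein genes, 8 fell and 1 rose, or 5 and 0 adjusted over the list alone (camera adjusted p = 0.0353; adjusted p = 0.400 with an estimated correlation). The share that fell was close to that over all genes, of which 1843 of 7696 were called lower in HUG1N. The median change of the list was only -0.08. RPS23 changed by -0.46 (SE 0.06) and RPL29 by -0.44 (SE 0.06). The ribosomal call was lost with quantile normalization (adjusted p = 0.0528), median centring (adjusted p = 0.0905), the mean of probe sets (adjusted p = 0.0533), the replicate number as a block (adjusted p = 0.0531), and without control replicate 2 (adjusted p = 0.0808) or shRNA replicate 1 (adjusted p = 0.0642). The NF-kB call was lost without HUG1N control replicate 2 (adjusted p = 0.0675), Caco-2 shRNA replicate 1 (adjusted p = 0.0643) or Caco-2 shRNA replicate 2 (adjusted p = 0.0544), with the replicate number as a block (adjusted p = 0.0513) and with the line fitted alone (adjusted p = 0.0606); over 17 settings the ribosomal values ran from 7.97e-06 to 0.0905 and the NF-kB values from 0.0150 to 0.0675.

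The remaining lists were not called in HUG1N. Of 27 immediate early and MAPK feedback genes, 4 rose and 12 fell (adjusted p = 0.0665), with FOSL2 at -1.56 (SE 0.11) and JUN at -0.96 (SE 0.08). Of 8 goblet and enteroendocrine genes, 5 rose and 1 fell (adjusted p = 0.0665), with AGR2 at 1.87 (SE 0.08) and TFF3 at 1.29 (SE 0.08). Of 27 genes for epithelial junctions and keratins, 14 rose and 3 fell (adjusted p = 0.0748), with KRT19 at 1.46 (SE 0.09) and JUP at -1.38 (SE 0.07). Of 23 cholesterol synthesis genes, 10 rose and 3 fell (adjusted p = 0.0795), with SC5D at 1.54 (SE 0.09) and INSIG1 at -1.41 (SE 0.14). Of 39 genes for DNA replication and G1/S, 12 rose and 6 fell (adjusted p = 0.186), with CDT1 at -1.12 (SE 0.11). Of 15 Wnt targets and stem cell genes, 7 rose and 1 fell (adjusted p = 0.264), with RNF43 at 1.42 (SE 0.15). Of 22 mesenchymal and matrix genes, 5 rose and 8 fell (adjusted p = 0.463), with TIMP1 at -1.63 (SE 0.12) and the smooth muscle actin gene ACTA2 at least 4.85-fold lower. Of 20 enterocyte genes, 5 rose and 2 fell (adjusted p = 0.410), with VIL1 at 1.15 (SE 0.11), and 9 of the 20 had no HUG1N array over log2 4. For these 8 lists the counts adjusted over the list alone were equal.

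Of 34 interferon response genes, 8 rose and 16 fell, or 9 and 16 adjusted over the list alone (adjusted p = 0.178), with PSMB9 at -2.04 (SE 0.15). Of 12 gastric genes, 2 rose and 5 fell, or 3 and 5 adjusted over the list alone (adjusted p = 0.340), with cathepsin E (CTSE) at -2.51 (SE 0.09) and CLDN18 at -2.71 (SE 0.13). Of 18 p53 targets, 6 rose and 7 fell, or 7 and 8 adjusted over the list alone (adjusted p = 0.854), with CDKN1A at -1.80 (SE 0.12). Of 29 unfolded protein response genes, 10 rose and 13 fell, or 13 and 13 adjusted over the list alone (adjusted p = 0.566), with the serine synthesis gene PHGDH at -2.44 (SE 0.10). Of 21 liver-type genes 3 rose and 3 fell, or 2 and 2 adjusted over the list alone (adjusted p = 0.812), and 15 had no HUG1N array over log2 4. Of 26 xenobiotic and steroid metabolism genes 3 rose and 6 fell, or 2 and 6 adjusted over the list alone (adjusted p = 0.634), and of 12 housekeeping genes 1 rose and 3 fell, or 1 and 2 adjusted over the list alone (adjusted p = 0.378). Counts were equal adjusted over the list alone for the other lists. Of 16 gut endoderm transcription factors 2 rose and 6 fell (adjusted p = 0.127), with the standing probe set of ELF3 at -0.93 (SE 0.10) and another at 0.40. Of 16 apolipoprotein genes 1 rose and 5 fell (adjusted p = 0.564), and 9 had no HUG1N array over log2 4. Of 20 BMP and TGF-beta targets 7 rose and 4 fell (adjusted p = 0.664), and of 21 apoptosis regulators 2 rose and 6 fell (adjusted p = 0.333). Median and mean had opposite signs for the BMP and p53 lists, and the apolipoprotein median was 0 with a mean of -0.36.

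Over all genes, limma called 3746 in HUG1N, 1903 higher and 1843 lower with the shRNA, of which 903 changed at least 2-fold. The count ran from 3026 to 3603 when any 1 array was left out.

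**Figure D2:**
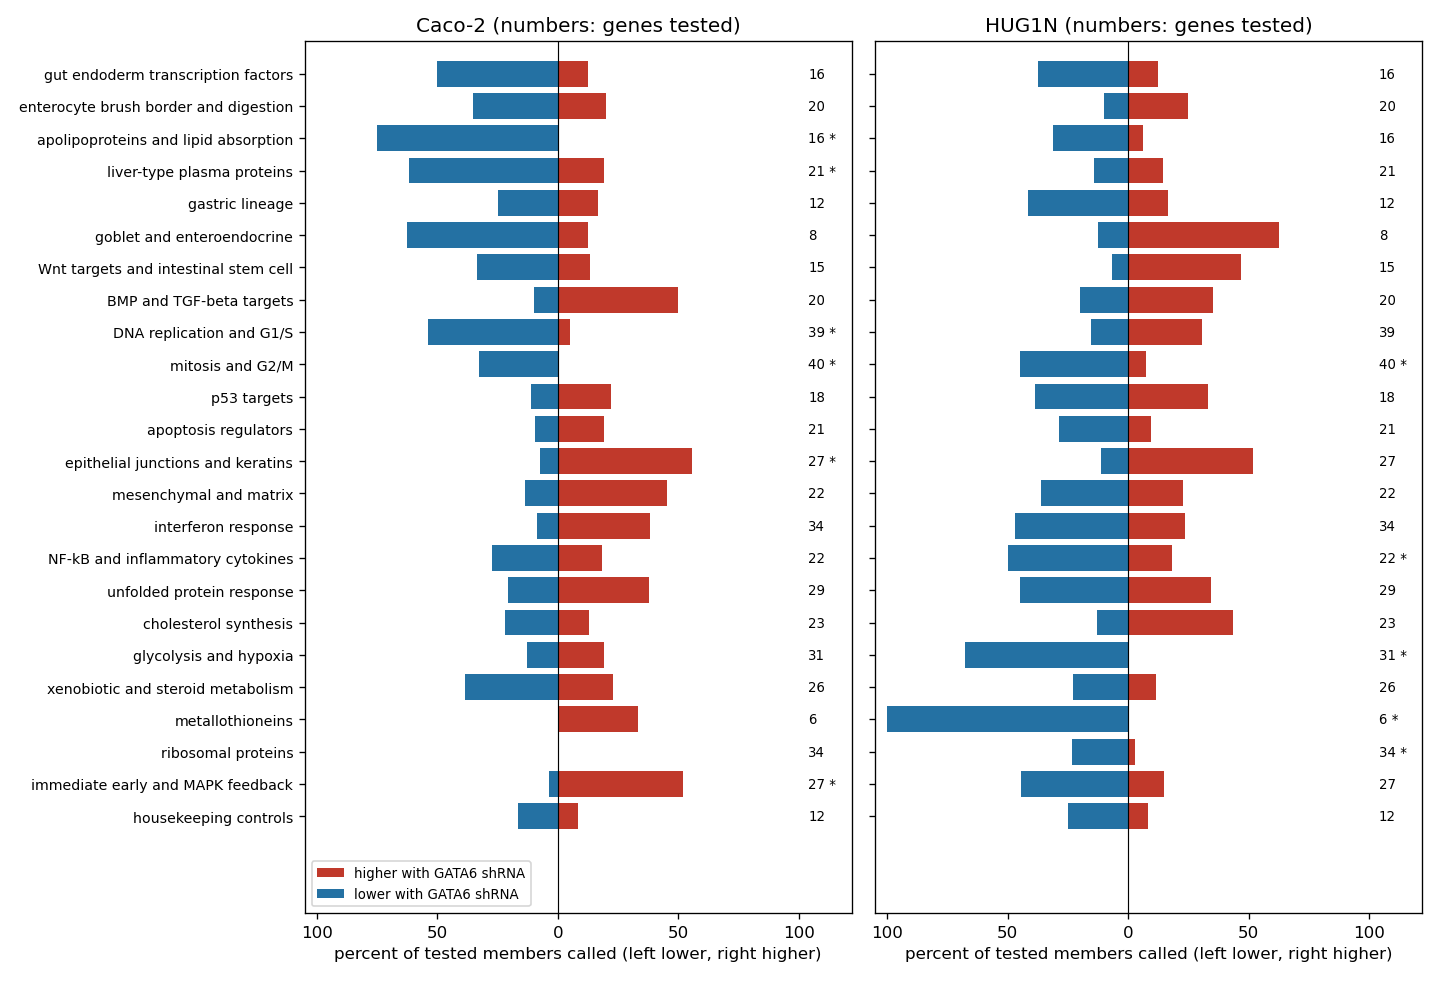
Percent of the tested members of each gene list that were called higher (right) or lower (left) with the GATA6 shRNA in each line; the numbers are genes tested and an asterisk marks lists called by camera with the preset correlation. In Caco-2, 12 of 16 apolipoprotein and lipid absorption genes were lower, and in HUG1N all 6 metallothioneins and 21 of 31 glycolysis and hypoxia genes were lower.

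The 2 lines shared part of their changes. F5, a coagulation factor gene, rose at least 5.46-fold in Caco-2 and at least 18.6-fold in HUG1N. BCL2L14, a member of the BCL2 family, fell at least 7.90-fold and at least 18.0-fold, and ROR1 fell at least 5.53-fold in Caco-2 and changed by -2.38 (SE 0.22) in HUG1N. The collagen-modifying enzyme gene P3H2 changed by 2.71 in Caco-2 and 3.06 in HUG1N (SE 0.22 each), and CLIC5 by 2.66 (SE 0.12) and at least 35.4-fold. FGFBP1, which releases fibroblast growth factors from the matrix, changed by 2.49 and 2.68 (SE 0.37 each), with 1 of the 2 HUG1N control arrays over log2 4. SLC35G2 changed by -2.57 and -2.49 (SE 0.10 each). The alkaline phosphatase gene ALPG rose at least 12-fold in Caco-2 and by 2.45 (SE 0.10) in HUG1N, with near-identical relatives. Other probe sets gave smaller changes for ALPG in Caco-2 (1.07), CLIC5 in HUG1N (3.36 and 0.94) and VGLL1 in Caco-2 (5.14, and 0 for a probe set at the floor). Those of ROR1 in Caco-2 (-0.53), LGR5 in Caco-2 (-0.29) and SLCO2B1 in HUG1N (0.03 and 0.32) were dim and changed little. Dim probe sets also gave smaller changes for ADAM22 in Caco-2 (-0.30 to 0), SIGLEC6 in Caco-2 (2.91 and 1.85), RAC2 in HUG1N (-0.10) and LCK in HUG1N (-0.98). In HUG1N, IL1A, IL23A, EFHC2 and RNASE1 each had another probe set at the floor with a change of 0.

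Of 1576 genes called in both lines, 1014 changed in the same direction (64.3%) and 562 in opposite directions. The shared rises numbered 484 against 371.9 expected of independent lists (odds ratio 1.60, one-sided Fisher's exact p = 1.68e-13). The shared falls numbered 530 against 353.9 (odds ratio 2.09, one-sided Fisher's exact p = 5.86e-31). These tests treat genes as independent, which they are not. Of the 1014, 124 changed at least 2-fold in both lines and 346 also differed in size between lines. Across all genes the changes correlated at r = 0.144 (Spearman's rho 0.151). The number changed in the same direction was 646 without Caco-2 control replicate 2.

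**Figure D3:**
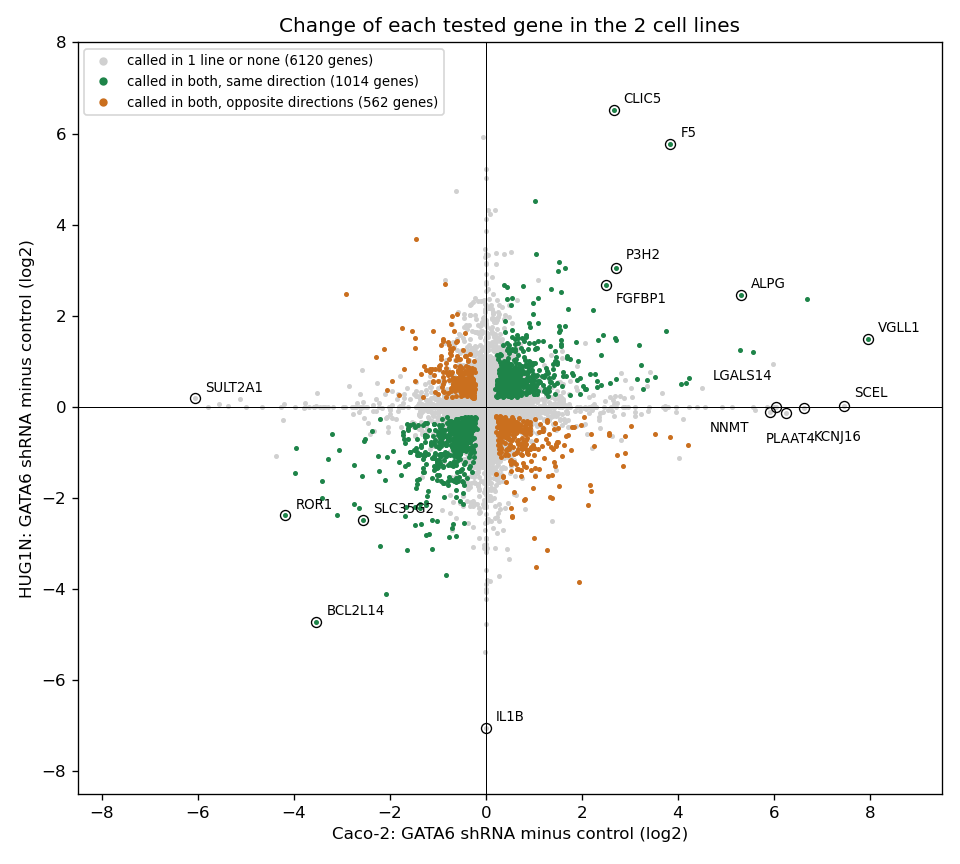
Log2 change of each of the 7696 tested genes with the GATA6 shRNA in Caco-2 (horizontal) and HUG1N (vertical), 1 point per gene, with the named shared genes and largest differences ringed. Genes called in both lines with the same direction (1014) outnumber those with opposite directions (562), and IL1B, SCEL and KCNJ16 lie along an axis, changed in 1 line.

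The lines also differed in many effects. SCEL rose in Caco-2 and stayed at the floor in HUG1N (2.08 in control and 2.10 in shRNA cells), so that its effects differed by -7.44 (HUG1N minus Caco-2; SE 0.10). KCNJ16 differed by -6.64 (SE 0.27), and LGALS14 by -6.05 (SE 0.26) in the same way. NNMT differed by -6.03 (SE 0.38), with 1 of the 2 arrays over log2 4 in each HUG1N group. IL1B lay near the floor in both Caco-2 groups (2.17) and fell in HUG1N, a difference of -7.04 (SE 0.11). SULT2A1 fell in Caco-2 and differed by 6.24 (SE 0.62). VGLL1 and PLAAT4 were already high in HUG1N controls (9.73 and 9.51) and differed by -6.48 (SE 0.14) and -6.38 (SE 0.13). The adjusted p of these 8 genes ran from 1.31e-06 to 7.79e-04. Because a gene at the floor cannot fall further, these sizes are not bounds on the true difference.

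As lists, glycolysis and hypoxia genes and immediate early and MAPK feedback genes had lower effects in HUG1N than in Caco-2 (camera adjusted p = 4.41e-05 each). DNA replication (adjusted p = 9.25e-04), goblet and liver-type genes (adjusted p = 0.00924 each) and apolipoproteins (adjusted p = 0.0237) differed towards higher values in HUG1N. In HUG1N 15 of the 21 liver-type and 9 of the 16 apolipoprotein genes had no array over log2 4 and could not fall. Falls of those genes in Caco-2 thus had to enter the differences, and the other members were not tested apart. Metallothioneins (adjusted p = 0.00333), interferon response and mesenchymal genes (adjusted p = 0.00438 each) and ribosomal proteins (adjusted p = 0.0175) differed towards lower values, where 8 of the 34 interferon response genes had no Caco-2 array over log2 4. With an estimated correlation the smallest of these values was an adjusted p = 0.183. The HUG1N ACTB gap of 3.73 in shRNA against 2.51 in control arrays moves with these differences.

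In all, 3457 genes had effects that differed between lines, 1707 higher and 1750 lower in HUG1N. Of these, 962 were called in Caco-2 alone, 1468 in HUG1N alone, 562 in both with opposite signs, 346 in both with the same sign and 119 in neither line.

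Control cells of the 2 lines differed in lineage genes. HUG1N controls had more LCN2, an iron-binding defence protein (at least 1455-fold), IGFBP3 (at least 568-fold), the aldo-keto reductase AKR1B10 (at least 1040-fold), TMC5 (at least 414-fold), TRIM31 (at least 475-fold) and the potassium channel KCNK1 (at least 626-fold). Caco-2 controls had more of the plasma protein genes AHSG (at least 2353-fold), FN1 (at least 1596-fold), FGG (at least 1257-fold) and SERPINA1 (at least 1112-fold), and of the apolipoproteins APOA1 (at least 2144-fold) and APOA2 (at least 1272-fold). Their adjusted p ran from 2.88e-09 to 1.10e-06. GATA6 did not differ by the test (-0.04, SE 0.10, limma adjusted p = 0.712).

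By list, 10 of 12 gastric genes, 31 of 34 interferon response genes, 19 of 22 NF-kB and cytokine genes and all 6 metallothioneins were higher in HUG1N controls. Caco-2 controls had higher values for 14 of 16 apolipoprotein genes, 17 of 21 liver-type plasma protein genes, 19 of 23 cholesterol synthesis genes and 28 of 40 mitotic genes. Over all genes 6032 differed, 2856 higher in HUG1N and 3176 higher in Caco-2, of which 3534 differed at least 2-fold. The ACTB gap was 1.92 in Caco-2 and 2.51 in HUG1N controls. Line and any difference in handling between lines cannot be separated here.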

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

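The tests of HUG1N RNA by ANXA1 and of RNA quality in HUG1N were chosen only after the results they bear on were seen; the others were set before their results were seen.

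The effect of the shRNA differed between the lines by limma's test of the difference for 3457 genes, and for 49 of the 53 genes named for the shRNA comparisons, with adjusted p up to 0.0249. The 53 were chosen for large changes in a line or between lines, so that share adds nothing to the evidence for a difference. Values below, in alphabetical order, are the fitted log2 effect in HUG1N minus that in Caco-2. For 45 of the 49 genes a group had no array over log2 4, so their values are neither sizes nor bounds and have no rank. Genes that fell further in Caco-2, or rose further in HUG1N, had positive values. They were ACP3 3.49, ADAM22 4.27, ADAM23 5.38, ATP10D 3.28, BTNL8 5.30, CFAP44 3.86, CLIC5 3.86 and DNAI7 4.14. DRC9 had 5.22, DZANK1 4.28, EFHC2 4.12, F5 1.92, HSD3B1 5.78, ITIH2 4.66, KANSL1L 4.27 and KRT20 4.15. LGR5 had 5.63, ROR1 1.79, RSAD2 5.97, SLC6A14 5.02, SLCO2B1 5.36, SULT2A1 6.24, TFF2 3.93 and VPS35L 4.99.

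Genes that rose further in Caco-2, or fell further in HUG1N, had negative values. They were ALPG -2.87, ALPP -4.31, ANXA1 -5.04, ATP6V1B1 -5.99, BCL2L14 -1.19, GREB1L -5.80, IFI27 -3.89 and IFIT1 -4.37. IL1A had -5.35, IL1B -7.04, IL23A -4.07, KCNJ16 -6.64, LCK -4.21, LGALS14 -6.05, MMP1 -2.03 and NNMT -6.03. PLAAT4 had -6.38, PLCB4 -3.99, POU5F1P3 -3.92, PPBP -5.86, RAC2 -4.76, RNASE1 -3.83, SCEL -7.44, SIGLEC6 -5.66 and VGLL1 -6.48. Of the 49 genes, 32 had no array over log2 4 in 1 of the lines, where a fall cannot be measured.

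GATA6 fell by 0.42 on the log2 scale in Caco-2 while 2982 genes were called. Compression of bright values on the array did not hide every larger fall. At the control brightness of GATA6, 6 of 476 genes were called with a fall of 1 log2 unit or more, FABP5 the furthest at -2.37. Over all genes in Caco-2 334 of 7696 were, and at the GATA6 brightness in HUG1N 26 of 483. The share in Caco-2 was below that over all genes, so compression of part of the GATA6 fall stays open. Signal from other transcripts on the GATA6 probe set itself is not excluded either. A fall of GATA6 protein larger than that of its RNA, and targets of the shRNA other than GATA6, were not tested, because the labels name 1 shRNA and no rescue. Differences between the groups in culture, in infection and in puromycin selection also stay open. The labels do not say what the control cells received.

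Several genes that Caco-2 controls barely showed rose in Caco-2 shRNA cells, among them placental genes and genes typical of HUG1N. RNA of whole placental tissue is argued against by the abundant placental transcripts CGA and CSH1, which stayed at the floor of 2.08. The 46 other placental markers with a probe set had a median change of 0 (quartiles 0 and 0.106). The floor largely set that median, since only 11 had a mean over log2 4 in Caco-2 shRNA arrays and 11 in control arrays. Of the 14 tested, 7 were called higher and 1 lower, against 1504 higher and 1478 lower of all 7696 genes. HUG1N RNA is argued against for ANXA1, since the share that ANXA1 would need (6.09%) predicts levels that 51 genes abundant in HUG1N and low in Caco-2 missed by a median of 4.41 log2 units (quartiles 3.33 and 5.09). The brighter probe set of KCNK1 changed by 2.66 in Caco-2, and its other probe set by 0.36. For KCNK1, HUG1N RNA cannot be told apart. The smaller share that its brighter probe set needs (0.466%) predicts a median level of only 4.07. That is close to log2 4, the limit used here for measurable values, against a median of 2.53 in Caco-2 controls. The median shortfall was 1.37 (quartiles 0.655 and 1.82). The rule set beforehand would have counted this shortfall for HUG1N RNA. It was set aside, because the predicted and control medians lay too close together for it to decide. That condition was not part of the rule. Cells that express some of these markers without the hormones, expression by the shRNA cells and a change in which cells survived selection stay open.

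The 3′ minus 5′ gap of ACTB was wider in HUG1N shRNA arrays, as given above, and the hybridisation controls were lower. The metallothioneins, whose transcripts are short, fell by 1.95 at the median (quartiles -2.17 and -1.86), further than the 5′ probe set of ACTB (-1.04). As 1 probe set gives no upper limit to such losses, lower RNA quality cannot be excluded for the metallothioneins. In equalised arrays losses in some genes raise intact RNA. Across the 4 poly-A spikes and the 3′ probe sets of ACTB and GAPDH, the largest gap from a control to an shRNA array of HUG1N was 1.87 log2 units. Part of that gap lies between replicates, since the spikes differed by up to 1.51 between the 2 control arrays. The group means of these references changed by -0.217 to 0.598. The gap of 1.87 is therefore a wide limit and not a measure of such a lift. The closest arrays of 65 genes lay further apart than 1.87. A change from a control near the floor has no fixed size, and how many of the 65 were near the floor was not counted. No conclusion about the lift is therefore drawn for the 65. For the other 335 of the 400 rises of 2-fold or more the lift cannot be told apart from the group, since they lie within 1.87. Nor can lower RNA quality be told apart for the other falls, since probe set positions are not known here. The dimmest of several bright probe sets changed by a median of -0.0126 relative to the brightest over 1898 genes (-0.00308 in Caco-2). A biological difference between the HUG1N groups stays open.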

How the results depend on the processing

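No test in this part was chosen only after the result was seen. Of 168 values of the main results under other settings, 145 kept their direction and side of the threshold or stayed within 1.5 times the count. For the genes named as the largest, shared or most different changes and control differences (80 values), all 1418 alternatives kept direction and call. The 80 values were chosen for their size on these same arrays, which favours that outcome. GATA6 is given separately, and genes named from lists were not run under alternatives. Limits come from signal over background, with 28.7 to 29.9% of probe sets per array at the floor, and from 2 arrays per group.

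Counts moved by construction with all probe sets tested singly (4489 in Caco-2, 5941 in HUG1N, 5408 for the difference, 9686 for the controls) and with a 2-fold minimum (742, 903, 1404, 3534 and 124 shared). Lists called by camera fell to 0 in both lines with an estimated correlation (3 in Caco-2 and 0 in HUG1N at an unadjusted p under 0.05) and rose to 19 in Caco-2 and 22 in HUG1N with fry, which tests lists against no change and not against other genes. GATA6 in Caco-2 (-0.42) was no longer called without a filter (adjusted p = 0.0562) or with the line alone (adjusted p = 0.0724), and GATA6 in HUG1N (-0.25) was called with an intensity trend and robust prior (adjusted p = 0.0346; 0.0346 to 0.271 over 18 alternatives). The cause was not tested.

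When each array was left out in turn, with the lone array assumed to vary like the other groups, genes called in Caco-2 ran from 1895 to 2974, genes changed the same way from 646 to 918, HUG1N lists from 3 (without control replicate 2) to 5, and GATA6 in Caco-2 from -0.52 to -0.31. GATA6 in HUG1N ran from -0.30 to -0.21. The low counts came without Caco-2 control replicate 1 (1985) or 2 (1895; 646 shared).

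The replicate numbers were not taken to pair the arrays. The deviations of same-numbered arrays correlated at 0.0662 in Caco-2 and -0.0161 in HUG1N across genes. With 2 pairs per line this correlation cannot establish a pairing. The 4 poly-A spikes ran with the number in HUG1N, higher in replicate 1 than 2 by 1.05 to 1.51 in control and 0.962 to 1.16 in shRNA arrays, but not in Caco-2 (-0.298 to -0.0336 in control, 0.192 to 0.298 in shRNA arrays). With the replicate number as a block, 2485 genes were called in Caco-2, 3391 in HUG1N, 2999 for the difference and 5925 for the controls. It left 3 HUG1N lists, without NF-kB (adjusted p = 0.0513) and ribosomal genes (adjusted p = 0.0531).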

Other observations

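The tests of cilia genes and placental markers used lists written after the first genes were seen and before the tests were run.

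Genes of motile cilia appeared among the leading rises in HUG1N shRNA cells, beyond those named in the comparison. The microtubule inner protein gene TEKT2 rose at least 6.83-fold. The kinase genes NEK11 and MAK, counted here with the cilia genes, rose at least 4.08-fold and 2.66-fold. These genes, and those named from the lists, were chosen after their values were seen. In a list of 48 other tested cilia genes, 22 rose and 4 fell, with a median of 0.37. The dynein heavy chain gene DNAH7 rose at least 1.77-fold and the intraflagellar transport gene IFT22 at least 2.93-fold. The dynein light chain gene DNALI1 changed by 2.07 (SE 0.11) and the transition zone gene TCTN1 by 2.02 (SE 0.11). IFT20 was the exception among the larger changes, at -1.36 (SE 0.09). The others called lower were BBS4 (-0.45), WDR19 (-0.43) and SPAG16 (-0.36). DRC4 (-0.62), TPPP3 (-0.41) and DNAH3 (-0.20) also had negative changes and were not called. In Caco-2, 2 of the 48 rose and 9 fell. The ACTB gap of these HUG1N shRNA arrays was 3.73 against 2.51 in their controls.

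A candidate explanation is that a wider set of cilia genes rose in HUG1N. With the genes seen first left out, camera gave p = 2.41e-04 in HUG1N (p = 0.0112 with an estimated correlation) and p = 0.136 in Caco-2. The difference between lines had p = 1.46e-04 (p = 0.010 with an estimated correlation). FOXJ1, the master regulator of motile cilia, stood at 0.74 (SE 0.34, limma adjusted p = 0.122), with 1 of the 2 control arrays over log2 4. This remains a hypothesis, since the pattern was noticed and tested on the same arrays.

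Among other placental markers in Caco-2 shRNA cells, TFAP2C changed by 4.24 (SE 0.11), GATA2 by 2.73 (SE 0.13) and GATA3 by 1.89 (SE 0.15), and the cancer-testis gene PAGE4 rose at least 4.24-fold. They too were chosen after their values were seen. Of 14 tested markers outside the genes seen first, 7 were called higher and 1, HSD3B1, lower. The 7 include TFAP2A at 0.52 (SE 0.16), whose Caco-2 arrays were all under log2 4. The list as a whole was tested only by its median, which the floor largely set, and not against other genes.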
